A study of Mus musculus with 16 samples.

How the data were processed

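Total RNA of sorted CD4+ FOXP3- Tcon and CD4+ FOXP3+ Treg from spleen and lymph node was sequenced on an Illumina NovaSeq, per the labels' protocols. There were 16 libraries: 4 replicates of each subset from mice on vehicle and 4 from mice on 50 mg/kg venetoclax for 14 days. Reads were mapped to mm10 with HISAT2 and handled with SAMtools, per the submitters' processing notes. Their versions, the read counter, its annotation and strand setting, the trimming and any filter on genes are not given in the sources used here. Each subset has its own table, so the 2 tables were normalized separately.

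The library columns hold the normalized signal per gene, which per the file headers and values is the authors' read count divided by 1 size factor per library. In each column every value was a whole multiple of 1 step, within a tolerance of 0.01, so the reads could be recovered. For 3 of the 8 Tcon columns (vehicle replicates 2 and 4 and venetoclax replicate 3) the size factor lies so close to 1 that an automated check of the step could not read it. There too all values were whole multiples of the step, while between 1.9% and 11.5% of the deposited values themselves were whole. The mean column is the authors' mean of these normalized signal values over the 8 libraries of a table. The tables also hold the authors' log2 fold change of venetoclax over vehicle with its standard error. These deposited log2 values are smaller in size than the ratios of group means, which is a sign of shrinkage. The method of shrinkage is not given in the sources used here. The deposited p-value columns hold the authors' unadjusted and adjusted p-value of that comparison, under column names that DESeq2 uses, and the test itself is not given. No sample column was left unused.

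The Tcon table had 11211 lines, of which 40 repeated another line exactly, leaving 11171 genes, and the Treg table had 11110, of which 43 did, leaving 11067. Spreadsheet dates stood in place of 18 symbols of Treg, which were restored through their Entrez identifiers. Identifiers matched the RefSeq annotation of GRCm38.p6 (the assembly of mm10) for 11168 Tcon and 11064 Treg genes, and coordinates are given from it, 1-based. Recovered reads ran from 22982210 to 24960570 per Tcon library and from 21335006 to 25027038 per Treg library. Counts of different libraries of a group varied more than counting alone allows (chi-square per degree of freedom of at least 6.2), so replicate spread, not depth, sets the precision of most genes. A count of 0 allows up to 3 reads, which covers counting error only.

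The following choices were made before the data were examined: the tests, the 19 program lists and 12 marker lists, the rule for named genes and the first set of alternatives. The design assumed read counts and edgeR as the first choice, with limma for normalized values. Since the tables hold normalized counts, limma was used, and edgeR and DESeq2 on the recovered reads became alternatives. Per subset, log2 of the normalized count plus a pseudocount of 1 was compared between 4 venetoclax and 4 vehicle libraries with limma's empirical Bayes test with a mean-dependent prior, and p-values were adjusted by Benjamini and Hochberg over all genes of the table, with a threshold of 0.05. The difference between subsets was tested as the interaction over all 16 libraries for the 10774 genes in both tables, after centring each table by 1 constant. Levels of Treg and Tcon in vehicle mice were set side by side as CPM without a test, as the design foresaw for normalized values; among the alternatives, edgeR and DESeq2 on the recovered reads tested Foxp3.

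Lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over all lists of a subset, and again with an estimated correlation and with fry. The program lists cover anti- and pro-apoptotic BCL-2 family genes, p53 targets, the Treg signature, naive, effector and memory, and T helper lineage genes, immediate early genes, cell cycle, interferon response, integrated stress response, chaperones, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cholesterol synthesis, common gamma chain signalling, NF-kB and TNF receptor signalling, and ribosomal proteins. The marker lists cover CD4 identity and other cells that the sort could hold. Per subset the text names the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 50 normalized counts and a symbol that is no predicted model (6 and 6 for the difference). It also names 10 genes fixed in advance (Bcl2, Bcl2l1, Mcl1, Bcl2a1b, Bcl2a1d, Bcl2l11, Foxp3, Cd4, Il2ra and Il7r) and, for each list, up to 4 members with the smallest p. Some genes that this rule takes in are not reported here.

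Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means. In Tcon all 4 same-number correlations of vehicle with venetoclax libraries were over 0.1 (0.12, 0.56, 0.61 and 0.27), so the number was read as pairing them, a reading that rests on these correlations and not on the labels. In Tcon 3 of the 4 pairs correlated best with their own number. Number 1 was the exception (0.12, against 0.25 with another number), so the pairing is uncertain. The Tcon and Treg libraries of a code correlated at 0.46 to 0.77, each best with its own code. The code was therefore used as a block in an alternative fit of the difference. The main fit of the difference held no block, and values of the difference come from it unless a block is named.

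Alternatives were the tool, the scaling (RLE and upper quartile), a minimum mean of 5 CPM, pseudocounts of 0.5 and 5, an adjusted p of 0.01, a fold of at least 1.5, the replicate block, a B cell score as a covariate, leaving out marker genes of other cells, and each library left out in turn. Added after the data were seen were the authors' deposited adjusted p, edgeR with TMM, with its filter and without, leaving out the libraries of replicate number 3, the summed level of Ddx3y and Kdm5d as a covariate, leaving out the 2 codes with partial Y-linked reads, the list test of the difference, and the overlap of the subsets under other splits of the codes. The sex of the mice is not given in the sources used here, and Y-linked reads were unevenly spread over the treatments.

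The procedure was tested on simulated counts with 200 changed genes drawn from the real means and library sizes. In Tcon limma recovered 3% of genes changed 1.25-fold, 53.7% of those changed 1.5-fold and 74.2% of those changed 2-fold, with 7 false calls among 94, on 11171 genes. In Treg the shares were 47.8%, 83.6% and 92.4%, with 9 false calls among 158, on 11067 genes. For the difference they were 10.4%, 41.8% and 80.3%, with 5 false calls among 93, on 10774 genes. DESeq2 on the same counts made 28 false calls among 132 in Tcon and 20 among 177 in Treg, and edgeR 9 among 96 and 10 among 160. The list test called the list that was moved and 0 of 30 unmoved lists in each subset. Genes were drawn independently of each other, so this does not show how the list test behaves where genes move together. On the real libraries, the other splits into 4 and 4 called a median of 8 lists in Tcon and 8.5 in Treg. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and matplotlib 3.10.9 were used, with random seed 1.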

Results

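RNA was sequenced from 2 subsets of CD4+ T cells sorted from the spleen and lymph nodes of mice that carry a GFP reporter of Foxp3: conventional cells (Tcon, FOXP3-) and regulatory cells (Treg, FOXP3+). The mice had received vehicle or 50 mg/kg of venetoclax, an inhibitor of the survival protein BCL-2, for 14 days. Each of the 4 groups held 4 libraries, 16 in all. Tcon and Treg libraries share the replicate codes VEH1 to VEH4 (vehicle) and ABT1 to ABT4 (venetoclax). The tables held 11171 genes in Tcon and 11067 in Treg, of which 10774 were in both. Reads assigned to these genes ran from 22982210 to 24960570 per Tcon library and from 21335006 to 25027038 per Treg library, and no gene took more than 2.1% of them (mt-Co1, the highest in every library, took 1.14% to 2.1%). Values below are normalized read counts (reads divided by 1 size factor per library), given as mean ± SD, and changes are venetoclax over vehicle on the log2 scale.

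The levels in vehicle mice describe the sorted populations before any comparison of treatments. Foxp3, the transcription factor that defines Tregs (Entrez 20371; chromosome X, 7579676 to 7595243, GRCm38.p6), stood at 837 ± 68 CPM (reads scaled to a common library total; SD, n = 4) in Treg and 29.1 ± 2.3 (SD, n = 4) in Tcon, 28.8-fold lower. Il2ra, the α chain of the interleukin-2 receptor, was at 1050 ± 38 in Treg and 7.46 ± 1.2 in Tcon. Il7r, the interleukin-7 receptor, was lower in Treg (257 ± 29) than in Tcon (619 ± 41), and Bcl2 was at 350 ± 24 in Treg and 220 ± 58 in Tcon. All 20 genes of the Treg signature list measured in both tables were higher in every vehicle Treg library than in every vehicle Tcon library. These levels are set side by side without a test, since the 2 tables were normalized separately; alternatives that did test Foxp3 on recovered reads gave an adjusted p of 8.85e-18 with edgeR and of 1.31e-08 with edgeR and the code as a block.

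Y-linked transcripts separated the replicate codes in both subsets, and the labels give no sex. Ddx3y and Kdm5d, Y-linked genes chosen after their values were seen, had a normalized count of at most 1 in vehicle replicates 1, 3 and 4 and in venetoclax replicate 4. Ddx3y stood at 5663.6 (Tcon) and 5326.4 (Treg) in vehicle replicate 2 and at 6674.1 and 5538.6 in venetoclax replicate 2. In venetoclax replicate 1 it was at 1467.8 and 1694.9, and in venetoclax replicate 3 at 3050.4 and 2871.6. Y-linked reads were therefore present in 1 of 4 vehicle codes and 3 of 4 venetoclax codes. Kdm6a, an X-linked gene that escapes inactivation, was lowest in the Tcon libraries of vehicle replicate 2 (2261) and venetoclax replicate 2 (2303).

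**Figure D1:**
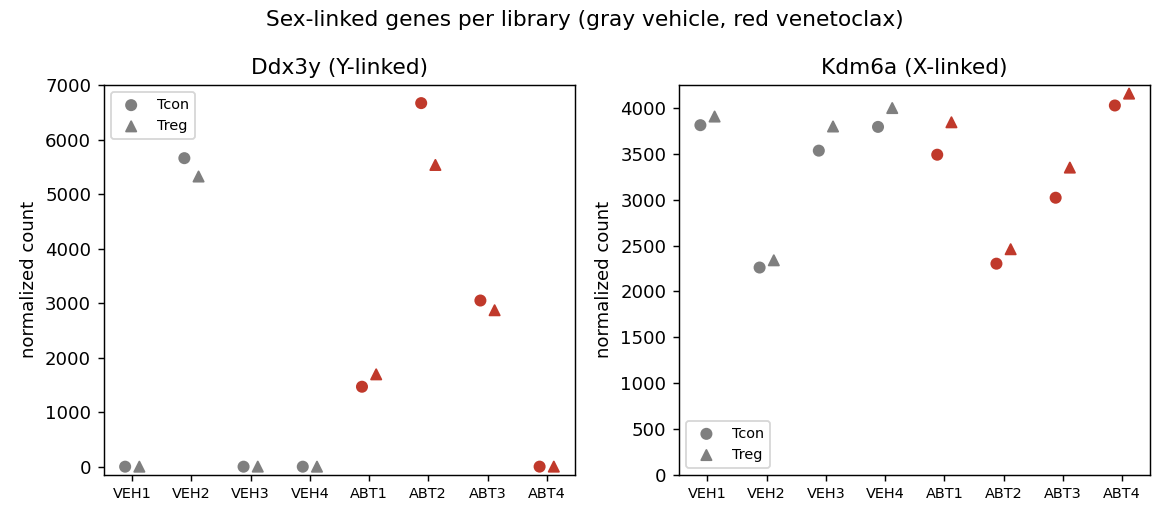
Normalized counts (y axis) of the Y-linked gene Ddx3y (left panel) and the X-linked gene Kdm6a (right panel) per replicate code (x axis). Each point is 1 library, with circles for Tcon, triangles for Treg, gray for vehicle and red for venetoclax. Venetoclax replicates 1 and 3 lie between the codes with at most 1 Ddx3y read and the codes at 5326.4 and above, in both subsets.

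The comparison in Tcon asks which transcripts differ in conventional CD4+ cells after 14 days of BCL-2 inhibition. Bcl2 itself, the drug's target (Entrez 12043; chromosome 1, 106538176 to 106714290), rose 2.18-fold, from 5192 ± 1280 to 11150 ± 1370 (SD, n = 4 per group), with all 4 venetoclax libraries above all 4 vehicle libraries (log2 1.13, SE 0.16, limma adjusted p = 0.00253). Of 40 cell cycle genes 33 rose (camera adjusted p = 2.07e-29; adjusted p = 0.159 with an estimated correlation): Top2a, the topoisomerase that untangles replicated DNA (Entrez 21973; chromosome 11, 98992947 to 99024199), went from 349.5 ± 45.3 to 1458 ± 366 (SD, n = 4 per group; log2 2.04, SE 0.16, limma adjusted p = 0.000336). Il2ra rose from 175.9 ± 24.2 to 351.9 ± 75 (log2 0.98, SE 0.16, limma adjusted p = 0.00589). Fosb, an immediate early AP-1 factor (Entrez 14282; chromosome 7, 19302696 to 19310118), fell from 2208 ± 1520 to 232.9 ± 155 (log2 -3.25, SE 0.64, limma adjusted p = 0.0139).

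In all, 772 of the 11171 genes passed limma's test in Tcon at an adjusted p of 0.05, 438 higher and 334 lower, and 179 of them moved more than 2-fold. With the replicate number as a block, if it pairs these libraries as their correlations were read, 1880 genes passed (997 higher, 883 lower), all 772 among them. DESeq2 called 1371 genes (686 higher, 685 lower), and the authors' deposited adjusted p called 1257, with 769 of the 772 among them. The count was 461 without vehicle replicate 1, 458 without vehicle replicate 2, 1244 without vehicle replicate 3, 306 without venetoclax replicate 1 and 415 without venetoclax replicate 2. Vehicle replicate 3 and venetoclax replicate 3 stood apart on the second principal component (-21.8 and -19, the other 6 libraries between 1.1 and 15.2), and 1443 genes passed without these 2. With the Y-linked level as a covariate 595 passed, 565 of them among the 772, and without venetoclax replicates 1 and 3, the codes with partial Y-linked reads, 116 did. Ddx3y and Kdm5d did not pass (log2 5.83, SE 3.11, adjusted p = 0.303 for Ddx3y).

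The largest rises in Tcon were in Drc1, a component of the dynein regulatory complex of cilia (Entrez 381738; chromosome 5, 30281335 to 30366695), and Neb, the giant actin-binding protein of muscle sarcomeres (Entrez 17996; chromosome 2, 52136640 to 52338798). Drc1 went from 61.3 ± 21.3 to 1193 ± 426 (SD, n = 4 per group; 18.9-fold, limma adjusted p = 0.000336), and Neb from 140.3 ± 61.4 to 1171 ± 436 (8.63-fold, adjusted p = 0.000943). Of the other 10 largest rises, 9 were Top2a and other genes of DNA replication and mitosis (Cenpf, Dtl, Kntc1, Tpx2, Pclaf, Aspm, Nusap1 and Kif11), between 2.04 and 2.58 on the log2 scale, and the last was Coro2a, a coronin that binds actin (2.13). Only gene counts were used here, and the strand setting is not given, so the rises of Drc1, Neb, Coro2a and, named below, Myo6 are not shown to come from full transcripts and not from short or overlapping ones. The 12 largest falls included Fosb, Plk2, a stress-induced polo-like kinase (-2.78), Dnajb9, a chaperone of the endoplasmic reticulum (-1.58), Gadd45b, a stress-inducible growth arrest gene (-1.42), the protease Prss12 (-1.75) and the glutamate receptor Grm6 (-1.43). Klf4 (-2.99), Bambi (-2.24), Maff (-1.75), Irs2 (-1.40), Arc (-1.39) and Rgs2 (-1.50) were called with all 8 libraries and lost the call when 1 was left out. Without vehicle replicates 1, 2 and 4 and venetoclax replicates 1 and 4, in turn, the adjusted p of Klf4 in Tcon was 0.0653, 0.0913, 0.0829, 0.0764 and 0.0621. That of Bambi in Tcon was 0.0724, 0.0764 and 0.0644 without vehicle replicates 1, 2 and 4, and 0.0617, 0.0612 and 0.0673 without venetoclax replicates 1, 3 and 4. Maff in Tcon stood at 0.0841 without vehicle replicate 2 and at 0.0916, 0.0992, 0.0593 and 0.074 without venetoclax replicates 1 to 4. For Irs2 in Tcon the values were 0.0619 and 0.0784 without vehicle replicates 1 and 2, and 0.085, 0.0795, 0.0852 and 0.0839 without venetoclax replicates 1 to 4. For Arc in Tcon they were 0.075 and 0.0865, and 0.0932, 0.075, 0.0906 and 0.0574, without the same libraries. For Rgs2 in Tcon only leaving out venetoclax replicate 1 ended the call (0.0534).

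Of the 7 anti-apoptotic BCL-2 family genes measured in Tcon, 2 rose over all genes tested and 3 rose adjusted over the list alone (median log2 0.08, camera adjusted p = 0.0398). The list's adjusted p = 0.361 with an estimated correlation. The second gene over all genes was Bcl2l1, which encodes BCL-XL and went from 444 ± 57.8 to 587.3 ± 7.81 (log2 0.41, SE 0.10, limma adjusted p = 0.0295). For Bcl2l1 in Tcon the adjusted p was 0.0773 without vehicle replicate 2, 0.062 without vehicle replicate 4, and 0.0947, 0.0819, 0.0627 and 0.0673 without venetoclax replicates 1, 2, 3 and 4. For the anti-apoptotic BCL-2 family list in Tcon it was 0.0612 without vehicle replicate 4 and 0.107 without venetoclax replicate 4. Mcl1, another anti-apoptotic member, had a log2 change of 0.02 (adjusted p = 0.917). Bcl2a1b (0.08) and Bcl2a1d (-0.01), near-identical copies whose reads the counting could split, did not pass. Of the 8 pro-apoptotic members none passed limma's test over all genes, 1 had an unadjusted p under 0.05, and DESeq2 called 1 and edgeR none (list median 0.15, adjusted p = 0.632). Bak1 rose adjusted over the list alone (log2 0.26, limma adjusted p over all genes = 0.0634), and over all genes with the replicate block (0.022). Bcl2l11, which encodes the BCL-2 antagonist BIM, had a log2 change of -0.21 (adjusted p = 0.413).

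Cell cycle was the list with the most single genes called in Tcon: 33 of the 40 measured rose and none fell over all genes, and 35 rose and 1 fell adjusted over the list alone (median log2 1.05, camera adjusted p = 2.07e-29). The list's adjusted p = 0.159 with an estimated correlation. Besides Top2a, Nusap1 and Kif11, Bub1, a kinase of the spindle checkpoint, went from 12 to 71.69 (log2 2.54) and Bub1b rose by 1.53. Of the 30 genes of the T cell receptor and immediate early response, 6 fell and none rose (12 fell and none rose adjusted over the list alone; median -0.69, camera adjusted p = 7.96e-07). That list's adjusted p = 0.542 with an estimated correlation, and with the replicate block 16 fell and 2 rose. Jund fell by 1.17 on the log2 scale, Ier2 by 0.83 and Ier5 by 0.72.

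Of 19 genes of common gamma chain cytokine signalling in Tcon, 5 rose over all genes and 6 adjusted over the list alone, none fell (7 rose and 2 fell with the replicate block), and the median was 0.17 (camera adjusted p = 0.00254; adjusted p = 0.542 with an estimated correlation). Il2rb, the β chain shared by the interleukin-2 and interleukin-15 receptors, went from 2201 to 4809 (log2 1.14), Cish, a feedback inhibitor induced by STAT5, from 368.6 to 1473 (2.02), and Socs2 rose by 1.05. Of 20 Treg signature genes, 7 rose over all genes (9 rose and 1 fell adjusted over the list alone; median 0.44, camera adjusted p = 0.000149; adjusted p = 0.159 with an estimated correlation), among them Gpr83 (1.01), Capg (0.65) and Il2ra. Foxp3 itself had a log2 change of 0.07 (adjusted p = 0.659). Of 30 effector and memory genes, 3 rose over all genes, Vim (0.77), Il2rb and Ccr8 (1.01), and 7 adjusted over the list alone, with 14 higher and 1 lower with the replicate block (median 0.34, camera adjusted p = 0.000149; adjusted p = 0.542 with an estimated correlation).

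Among 23 genes of the unfolded protein response and chaperones in Tcon, 4 rose and 1 fell over all genes (6 and 1 adjusted over the list alone, 7 and 2 with the replicate block; median 0.14, camera adjusted p = 0.0173; adjusted p = 0.542 with an estimated correlation). The heat shock proteins Hsph1 (2366 to 8348, log2 1.91), Dnaja1 (9770 to 21490, 1.12) and Hspd1 (0.69) rose, while Dnajb9 fell. Glycolysis (20 genes; 1 rose, 1 fell; 5 and 1 adjusted over the list alone; 6 and 1 with the block) had a median of 0.18 and a camera adjusted p of 0.0194 (adjusted p = 0.542 with an estimated correlation). Its fall was Pdk1, which restrains pyruvate oxidation (-0.51). Cholesterol synthesis (20 genes; 0 rose, 1 fell; 6 and 1 adjusted over the list alone; 7 and 1 with the block) had a median of 0.22 and a camera adjusted p of 0.0156 (adjusted p = 0.794 with an estimated correlation). Leaving out 1 library ended these calls as follows: the unfolded protein response and chaperones list in Tcon without vehicle replicate 3 (0.0861), the glycolysis list in Tcon without venetoclax replicate 3 (0.0668), and the cholesterol synthesis list in Tcon without vehicle replicate 4 (0.0612), venetoclax replicate 2 (0.0536) or venetoclax replicate 3 (0.0668). With the Y-linked level as a covariate the cholesterol synthesis list in Tcon had an adjusted p of 0.0531.

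In total 9 of the 23 lists tested in Tcon passed camera's test with its preset correlation, 8 higher and 1 lower, and 3 passed with fry. None passed with an estimated correlation, where 3 of the 9 had an unadjusted p under 0.05. With the replicate block 13 passed; the 4 that came in were naive and resting T cell genes (17 measured, 1 rose, 6 fell, median -0.05; adjusted p = 0.052 without the block, 0.014 with it), interferon response (35, 2 fell, or 11 with 1 higher with the block, -0.11; 0.052 and 0.013), mitochondrially encoded genes (12, -0.20; 0.0667 and 0.0241) and cytosolic ribosomal protein genes (71, -0.11; 0.052 and 0.000768). In the last 2 lists no single gene was called by limma, DESeq2 or edgeR, and none had an unadjusted p under 0.05. Their medians turned positive without vehicle replicate 3 (0.05 for mitochondrially encoded and 0.06 for cytosolic ribosomal protein in Tcon). Igfbp4, one of the naive list, rose from 15120 to 35230 (log2 1.23). The p53 target list (15 measured, 2 rose, 1 fell, adjusted p = 0.619) had a median of 0.08 and a mean of -0.08, and the integrated stress response (26 measured, 4 rose, 3 fell, adjusted p = 0.747) a median of 0.03 and a mean of -0.02. In the latter, Ddit4, an inhibitor of mTORC1, went from 4349 to 12420 (log2 1.57), whereas Trib3 fell by 0.86. No member of the T helper lineage list (18 measured, median 0.26, adjusted p = 0.226) passed limma's test; 4 had an unadjusted p under 0.05, DESeq2 called 2, edgeR none and limma with the block 4. For oxidative phosphorylation (68, -0.02, 0.918) limma, DESeq2 and edgeR called no member and 1 had an unadjusted p under 0.05. In addition 2 of 26 NF-kB and TNF receptor genes rose and, with the block, 4 fell (median -0.05, adjusted p = 0.581). None of 47 markers of other cell types was called by limma in Tcon (6 at an unadjusted p under 0.05, 4 with the block, 1 by the authors' deposited adjusted p); their median was 0. The CD4 identity list had a median of -0.01, with Cd5 lower (-0.39, adjusted p = 0.00769).

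**Figure D2:**
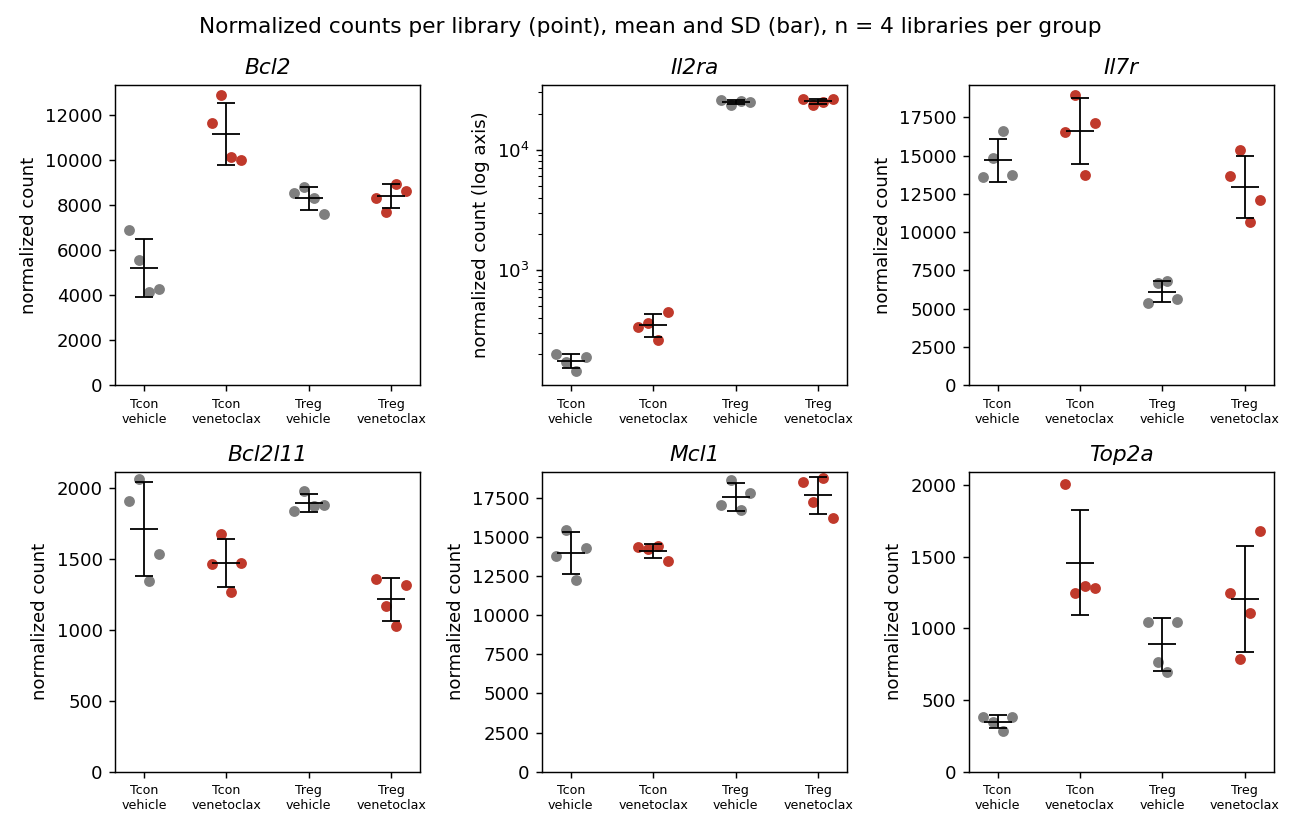
Normalized counts of Bcl2, Il2ra (log axis), Il7r, Bcl2l11, Mcl1 and Top2a per library in the 4 groups, with the mean and SD of 4 libraries per group. Bcl2, Il2ra and Top2a are higher after venetoclax in Tcon, Il7r is higher and Bcl2l11 lower in Treg, and Mcl1 shows neither.

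The comparison in Treg asks the same of regulatory cells. Il7r, which conveys the interleukin-7 survival signal (Entrez 16197; chromosome 15, 9506159 to 9529941), rose 2.11-fold, from 6108 ± 707 to 12930 ± 2010 (SD, n = 4 per group; log2 1.08, SE 0.10, limma adjusted p = 7.83e-05). Bcl2l11 (Entrez 12125; chromosome 2, 128126038 to 128162547) fell from 1892 ± 62.2 to 1216 ± 152 (log2 -0.65, SE 0.08, limma adjusted p = 0.000224). Bcl2 was at 8298 ± 508 with vehicle and 8376 ± 539 with venetoclax (log2 0.01, SE 0.06, adjusted p = 0.899), and Foxp3 at 19840 ± 1440 and 21360 ± 141 (0.11, adjusted p = 0.202). Of 71 cytosolic ribosomal protein genes, 61 fell (camera adjusted p = 1.28e-21; adjusted p = 0.489 with an estimated correlation).

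In all, 2164 of the 11067 genes passed limma's test in Treg, 1189 higher and 975 lower, and 108 of them moved more than 2-fold. The count was 1419 without vehicle replicate 3 and 1327 without venetoclax replicate 1. Upper quartile scaling, which shifted the median of all genes to -0.025, gave 970 higher and 1357 lower, 41.7% higher against 54.9% with the deposited scaling. DESeq2 called 2422 genes, and the authors' deposited adjusted p called 2270, with 2103 of the 2164 among them. With the Y-linked level as a covariate 2132 passed, 1932 of them among the 2164, and 614 without venetoclax replicates 1 and 3. Without both libraries of replicate number 3 it was 1028. Ddx3y had a log2 change of 5.57 (SE 2.67) and did not pass.

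The largest rise in Treg was in the heat shock protein Hsph1 (Entrez 15505; chromosome 5, 149616843 to 149636498), from 1983 ± 858 to 9455 ± 3210 (SD, n = 4 per group; log2 2.28, SE 0.28, limma adjusted p = 0.000275). The co-chaperones Dnaja1 (1.32) and Stip1 (1.24) rose as well, as did the chemokine receptor Cxcr4 (2869 to 6837, 1.31) and Il1rl1, the interleukin-33 receptor (394.1 to 927.1, 1.23). Other large rises were Frmd5 (1.64), Trf (1.62), Arrdc4 (1.29), Adam8 (1.19) and the near-identical copies Lilrb4a (1.43) and Lilr4b (1.19), whose reads the counting could split. The 12 largest falls held the AP-1 genes Fosb (-3.57), Fos (-2.44), Jun (-1.76) and Junb (-1.65), with Klf4 (-3.16), Plk2 (-2.36), Bambi (-2.15), Ppp1r15a (-2.11), Rgs2 (-1.45), Rhob (-1.28), Rgcc (-1.25) and the phosphatase Dusp1 (-1.24). For Dusp1 in Treg the adjusted p was 0.0513 without venetoclax replicate 3 and 0.0502 without venetoclax replicate 4. By the authors' deposited adjusted p, neither Jun in Treg (0.0692) nor Dusp1 in Treg (0.0807) was called.

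Of the 7 anti-apoptotic genes in Treg, 1 rose, over all genes and adjusted over the list alone: Bcl2a1b (log2 0.25, adjusted p = 0.0409), whose reads a near-identical copy may share. For Bcl2a1b in Treg the adjusted p was 0.0504, 0.0858 and 0.116 without vehicle replicates 1, 2 and 3, and 0.0746, 0.0511 and 0.114 without venetoclax replicates 2, 3 and 4. The list had a median of 0.14 and did not pass (adjusted p = 0.194). Mcl1 (0.01, adjusted p = 0.953) and Bcl2l1 (0.10, adjusted p = 0.337) did not pass. Of 8 pro-apoptotic genes, 1 rose and 2 fell on both counts: Bak1 rose by 0.25 and Bax fell by 0.19 on the log2 scale beside Bcl2l11. The list's median was 0.06 and its mean -0.01 (adjusted p = 0.711). Bak1 in Treg had an adjusted p of 0.0596 without venetoclax replicate 4, and Bax in Treg had 0.0596 without vehicle replicate 1, 0.0611 without venetoclax replicate 1 and 0.0655 without venetoclax replicate 4.

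Of 30 effector and memory genes in Treg, 17 rose and 1 fell over all genes (19 and 2 adjusted over the list alone; median 0.49, camera adjusted p = 2.11e-09; adjusted p = 0.234 with an estimated correlation), among them Ccr4 (1620 to 3069, 0.93), Il2rb (25760 to 39490, 0.61), Maf (0.91) and Icos (0.50). Of 22 Treg signature genes, 14 rose and none fell (15 adjusted over the list alone; median 0.29, camera adjusted p = 4.13e-09; adjusted p = 0.234 with an estimated correlation), including Nt5e (0.62), Itgae (0.73) and Klrg1 (1.08). Of 15 T helper lineage genes, 9 rose (11 rose and 2 fell adjusted over the list alone; median 0.54, camera adjusted p = 2.31e-05; adjusted p = 0.234 with an estimated correlation), with Pdcd1, the PD-1 receptor (0.92), and Ccr6 (0.70) among them. Of 17 naive and resting genes, 9 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.21, camera adjusted p = 7.49e-06; adjusted p = 0.234 with an estimated correlation). The chromatin organizer Satb1 fell from 9534 to 5963 (-0.68) and Foxo1 fell by 0.36, and the member that rose was Il7r. Common gamma chain signalling (19 genes, 6 rose; 6 rose and 1 fell adjusted over the list alone; median 0.06) had a camera adjusted p of 0.0399 (adjusted p = 0.489 with an estimated correlation). That call, for the common gamma chain cytokine signalling list in Treg, ended without vehicle replicate 2 (0.072) or venetoclax replicate 1 (0.0687).

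Several lists moved down in Treg. The 71 ribosomal protein genes had a median of -0.27 (61 fell over all genes and 68 adjusted over the list alone, camera adjusted p = 1.28e-21; adjusted p = 0.489 with an estimated correlation), with Rps13 at -0.29 and Rps24 at -0.33; pseudogene copies make the single values uncertain. Of 68 nuclear genes of oxidative phosphorylation, 9 fell (7 adjusted over the list alone; median -0.14, camera adjusted p = 2.11e-09; adjusted p = 0.496 with an estimated correlation). Of 12 mitochondrially encoded genes, 5 fell (11 adjusted over the list alone; median -0.25, camera adjusted p = 7.98e-06; adjusted p = 0.489 with an estimated correlation), with mt-Nd3 at -0.35 and mt-Nd6 at -0.38. Of 30 immediate early genes, 14 fell and 3 rose (17 and 3 adjusted over the list alone; median -0.36, camera adjusted p = 6.97e-06; adjusted p = 0.489 with an estimated correlation). The AP-1 gene Jund fell by 0.75 on the log2 scale, whereas Irf4, an activation-induced transcription factor, rose by 0.61. Of 35 interferon response genes, 14 fell and 4 rose (16 and 4 adjusted over the list alone; median -0.23, camera adjusted p = 0.000717; adjusted p = 0.616 with an estimated correlation), with Usp18 at -0.61 and Ifi213 at -0.59 among the falls and Gbp3 at 0.46 among the rises. Of 20 cholesterol synthesis genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.14, camera adjusted p = 0.00898; adjusted p = 0.557 with an estimated correlation), with Insig1 at -0.47 and Nsdhl at -0.41. The cholesterol synthesis list in Treg had an adjusted p of 0.0517 without venetoclax replicate 1.

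Of 23 genes of the unfolded protein response and chaperones in Treg, 8 rose, 1 fell and 14 were not called over all genes. Adjusted over the list alone, 10 rose and 1 fell. The list's median was 0.12 (camera adjusted p = 0.00366, and 0.489 with an estimated correlation). Hspd1 rose by 0.73 and Hsp90b1 by 0.37, while Dnajb9 was again the member that fell (-1.10). Cell cycle genes did not pass as a list (40 measured, 2 rose, 1 fell, 1 rose adjusted over the list alone; median 0.20, adjusted p = 0.108). Neither did p53 targets (16 measured, 5 rose, 2 fell; median 0.09, mean -0.09, adjusted p = 0.235), the integrated stress response (25, 1 rose, 3 fell; -0.04, 0.429), glycolysis (20, 3 rose, 2 fell; -0.01, 0.76) or NF-kB and TNF receptor signalling (26, 7 rose, 4 fell; 0.07, 0.194). In these lists Ddit4 (1.16) and Malt1 (0.31) rose, and Plk2 and Pdk1 (-0.65) fell. In total 12 of 24 lists passed with the preset correlation, 5 higher and 7 lower, and 7 with fry. None passed with an estimated correlation, where 4 of the 12 had an unadjusted p under 0.05. Of 39 genes on the marker lists of other cells, 5 were called: Cd74 (0.53), Cd22 (0.60), Cybb (0.71), Ctsh (1.57) and Pecam1 (-0.44). The median was 0.34, with an SE of 0.1 over genes, which leaves out the spread between libraries. These calls do not show other cells. Pecam1 stood at 236 CPM in vehicle Treg and 260 in vehicle Tcon. Cd74 was at 46.4 CPM in vehicle Treg, with H2-Aa, H2-Ab1 and H2-Eb1 below 1. Which cells held these transcripts was not tested. For Cd22 in Treg the adjusted p of 0.0199 became 0.0601 without vehicle replicate 1, 0.0608 without vehicle replicate 3, 0.055 without venetoclax replicate 2 and 0.0559 without venetoclax replicate 4. In the CD4 identity list (median -0.05) Cd28 was higher (0.28) and Themis lower (-0.43).

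**Figure D3:**
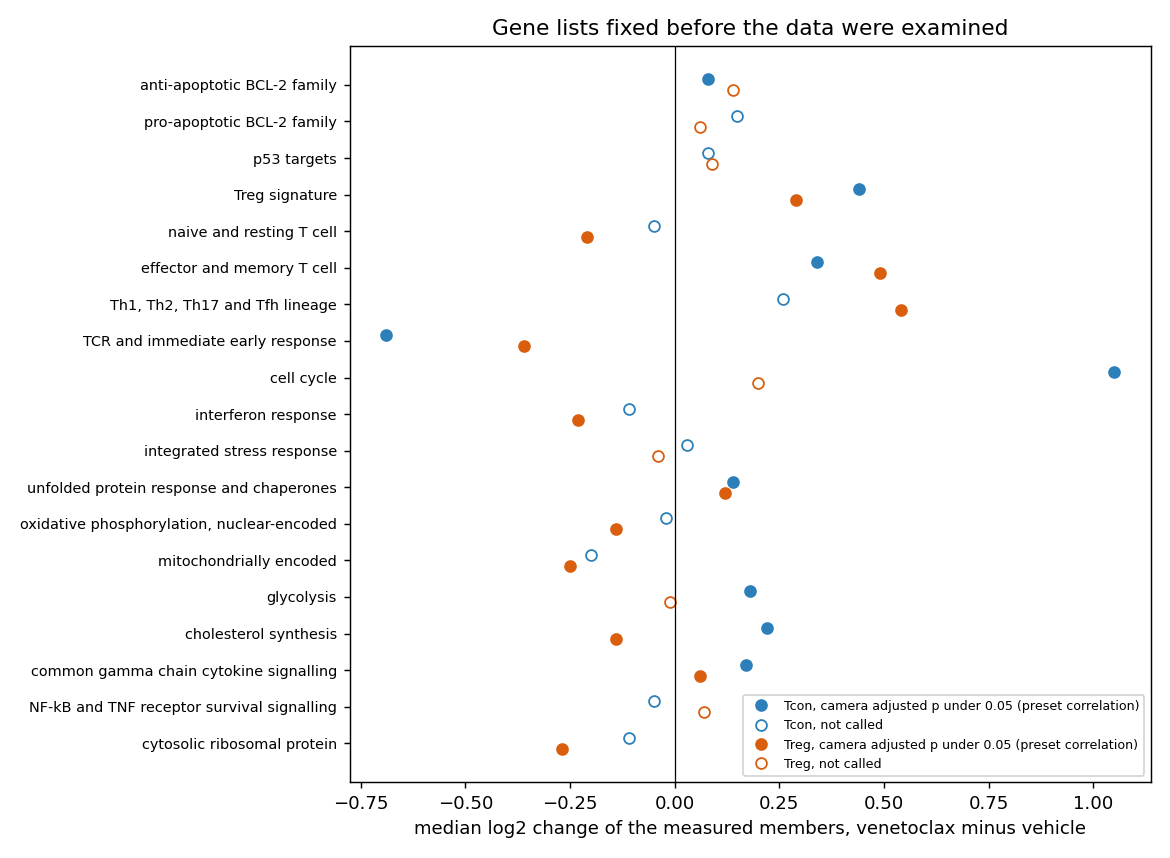
Median log2 change (venetoclax over vehicle) of the 19 gene lists in Tcon (blue) and Treg (orange), where filled points passed camera's test with its preset correlation. Cell cycle genes have the highest median in Tcon (1.05) against 0.20 in Treg, and the immediate early list is low in both (-0.69 and -0.36).

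By median log2 change in Tcon and Treg, in that order, the marker lists of other cells ran as follows: B cell -0.04 and 0.10 (-0.02 in Treg with upper quartile scaling), MHC class II -0.03 and 0.55, plasma cell -0.13 and 0.09, myeloid 0.14 and 0.10, neutrophil 0.63 and 0.62, dendritic -0.34 and 0.59, CD8 T cell 0.01 and -0.80, NK 0.06 and 0.17, erythroid -0.06 and 1.39, platelet -0.24 and -0.14, and stromal 0.63 and 0.28. Some of these values rest on 1 gene: platelet in both subsets and dendritic in Treg. Others rest on 2 genes: neutrophil and CD8 T cell in both subsets, and NK and plasma cell in Treg. The erythroid value in Treg has an SE between libraries of 1.32. Such medians do not show that a whole cell type shifted. Without a block, no marker list large enough for camera passed its test in either subset. The lowest adjusted p was 0.056, for MHC class II in Treg. The myeloid list in Tcon had a median of 0.14 and a mean of 0.06, and camera's direction was down (adjusted p = 0.997).

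The third comparison asks whether the 2 subsets respond differently to the drug, by testing the difference of the effects, Treg minus Tcon. The Bcl2 response was lower in Treg by 1.11 (difference of log2 changes -1.11, SE 0.18, limma adjusted p = 0.00487), and that of Il2ra likewise (-0.96, SE 0.17, limma adjusted p = 0.00857). The Il7r response was higher in Treg (0.91, SE 0.17, limma adjusted p = 0.0106). These p-values are from the fit without the code block. With the block, limma's adjusted p was 0.00301 for Bcl2, 0.00346 for Il2ra and 0.000109 for Il7r. Drc1 differed most (-3.73, SE 0.37, limma adjusted p = 6.2e-05). Myo6, an actin motor, had a log2 change of 1.76 in Tcon and -0.48 in Treg, a difference of -2.24 (SE 0.27, limma adjusted p = 0.000612). Mcl1 (-0.01), Bcl2l1 (-0.32), Bcl2l11 (-0.44, adjusted p = 0.325), Bcl2a1b (0.17), Bcl2a1d (0.17), Foxp3 (0.04) and Cd4 (0.03) showed no difference that passed.

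Over the 10774 genes in both tables, 140 differed in the fit without a block, 36 with a higher response in Treg and 104 with a lower one. With the replicate code as a block, which pairs the Tcon and Treg libraries of a code, 389 differed (137 and 252), 139 of the 140 among them, and DESeq2 called 295. In the fit without the block, the count was 56, 72 and 73 without vehicle replicates 1, 2 and 4. It was 44, 43 and 65 without venetoclax replicates 1, 2 and 3. A minimum mean of 5 CPM left 88. With the Y-linked level as a covariate it was 89, and without venetoclax replicates 1 and 3 it was 4 (Il2ra, Rcn1, Gpr34 and Drc1). The difference for Il2ra Treg minus Tcon had an adjusted p of 0.0644 without venetoclax replicate 2, and that for Il7r Treg minus Tcon one of 0.075 without venetoclax replicate 1.

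The other large differences were lower responses in Treg of Fsd1l (-2.60) and of the mitotic genes Bub1 (-2.31), Nuf2 (-2.29) and Kif4 (-2.27). Higher responses were those of Prss12 (1.99), the integrin Itga7 (0.99), Trim13 (0.98), the linker histone H1f0 (0.94) and Zfp316 (0.91). Each of these 9 lost its call in the fit without the code block when 1 code was left out, with adjusted p values in the ranges given here. Fsd1l Treg minus Tcon had 0.0551 to 0.0896 without vehicle replicate 1 or 4 or venetoclax replicate 1, 2 or 3. Bub1 Treg minus Tcon had 0.0521 to 0.166 without any code but venetoclax replicate 4. Nuf2 Treg minus Tcon (0.0523 to 0.115), Itga7 Treg minus Tcon (0.0753 to 0.224) and Trim13 Treg minus Tcon (0.0782 to 0.169) lost it without vehicle replicates 1, 2 or 4 or venetoclax replicates 1, 2 or 3. Kif4 Treg minus Tcon had 0.0607 to 0.169 without vehicle replicate 1 or 2 or venetoclax replicate 1, 2 or 3, and Prss12 Treg minus Tcon had 0.0553 to 0.0878 without vehicle replicate 1, 2 or 4 or venetoclax replicate 1 or 3. H1f0 Treg minus Tcon had 0.0501 without vehicle replicate 2, 0.0598 without venetoclax replicate 1 and 0.0647 without venetoclax replicate 2, and Zfp316 Treg minus Tcon had 0.0932 to 0.165 without any code but vehicle replicate 3.

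**Figure D4:**
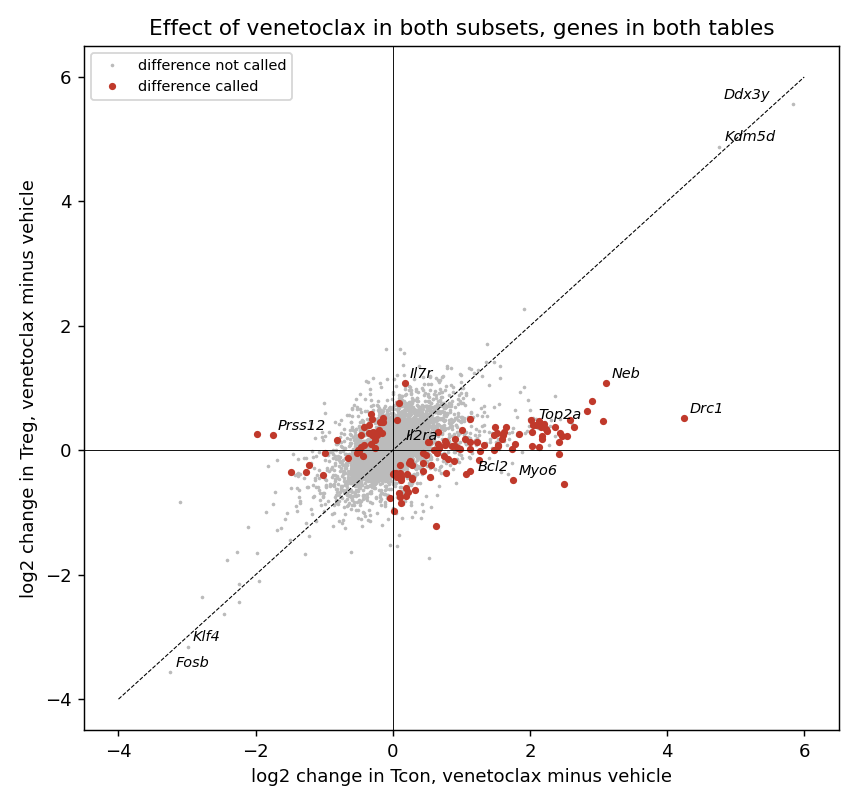
Log2 change in Treg (y axis) against Tcon (x axis) for the genes in both tables, venetoclax over vehicle, 1 point per gene, red where the difference passed limma's test and a dashed line where both are equal. Bcl2, Il2ra, Top2a and Drc1 lie below the line and Il7r above it.

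Cell cycle genes as a list responded less in Treg: 13 of 40 were lower over all genes, 23 with the code block and 30 adjusted over the list alone (median difference -0.92, camera adjusted p = 3.7e-32; adjusted p = 0.202 with an estimated correlation). This list test was added after the data were seen, and 7 of 23 lists passed it, 1 higher and 6 lower. The others were cholesterol synthesis (median difference -0.28, none over all genes, 7 lower with the code block and 7 adjusted over the list alone, camera adjusted p = 2.13e-08; adjusted p = 0.388 with an estimated correlation), glycolysis (-0.15; none over all genes, 3 with the code block and 1 adjusted over the list alone; 0.000305; adjusted p = 0.287 with an estimated correlation), ribosomal protein genes (-0.16, 0.000172) and oxidative phosphorylation (-0.11, 0.00021), both with adjusted p = 0.82 with an estimated correlation and no member called on either count (2 lower among the former with the code block). T helper lineage (0.16, no member called) and common gamma chain signalling (-0.11; 1 higher and 2 lower over all genes, 1 and 3 adjusted over the list alone) each had a camera adjusted p of 0.0134, and adjusted p = 0.601 with an estimated correlation. The immediate early list did not pass (median difference 0.14, adjusted p = 0.145), and passed with the code block (0.0423), as did the interferon response (-0.08; 0.229 without the block, 0.0423 with it). The remaining program lists had adjusted p values of 0.0739 (naive and resting) and above.

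Of the genes in both tables, 187 rose in both subsets and 201 fell in both, while 6 rose in Tcon and fell in Treg and none went the other way. Equally long lists of top genes from the 34 other ways of dividing the 8 codes into 4 and 4, a comparison added after the data were seen, shared 71 to 284 genes higher in both and 45 to 182 lower in both, and 0 to 32 and 0 to 26 in the opposite directions. Across 9661 genes, which are not independent replicates, the log2 changes of the subsets had r = 0.63, within the range of 0.24 to 0.70 given by the same 34 divisions. The covariance was 0.0505, above the highest of those (0.0393).

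**Figure D5:**
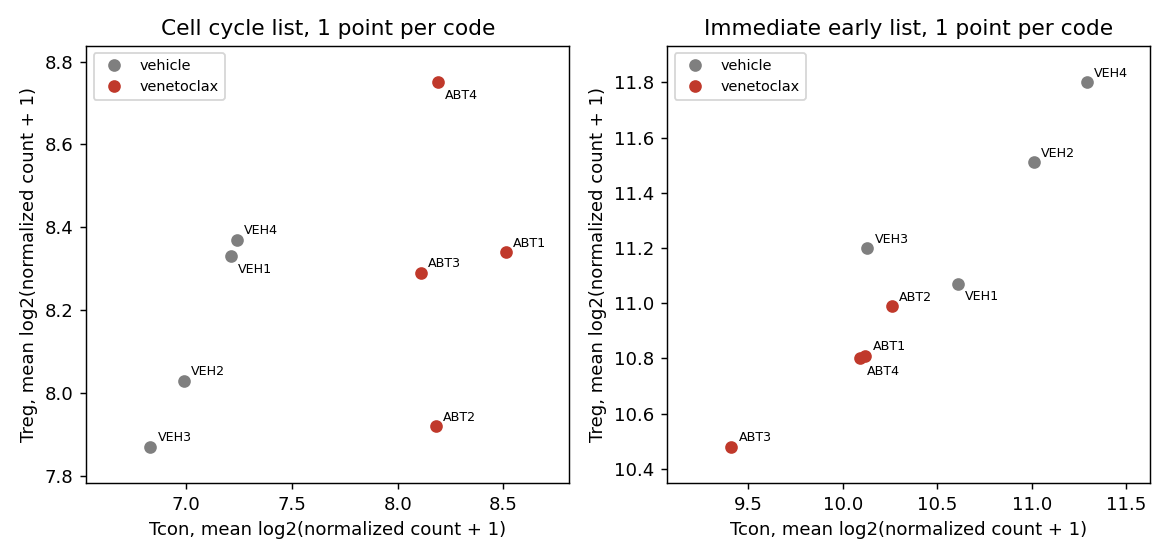
Mean log2 score of the cell cycle and immediate early lists per replicate code in Tcon (x axis) and Treg (y axis), gray for vehicle codes and red for venetoclax codes. The cell cycle scores separate the treatments along the Tcon axis, and the immediate early scores of a code move together in both subsets.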

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

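The tests of dissociation stress, handling, sex, carried-over cells and partial Y-linked reads, the list test of the difference with its splits and the splits of single lists were chosen only after the result was seen; the other counts over splits of the libraries were planned.

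Of 176 groups of 4 libraries checked for a library far from the other 3, 12 held one, where chance alone gives about 1 in 20 groups, or 8.8. In Tcon of venetoclax replicate 1, mitotic genes stood above the other venetoclax libraries: Nusap1 at 225.5 (others 129 to 141.9), Bub1 at 88.67 (64.2 to 67.4), Kif11 at 385.8 (232.9 to 256.8) and Top2a at 2006 (1249 to 1296), and Cd4 was at 26860 (25890 to 25970). In Tcon of vehicle replicate 3, Cd4 was low at 21970 (25050 to 25530) and Nuf2 high at 14.8 (8.94 to 9.83). Itga7 was high in Tcon of vehicle replicate 2 at 318.9 (204.6 to 217.3), and Trim13 in Tcon of venetoclax replicate 4 at 128.4 (116 to 116.9). In Treg of vehicle replicate 2, Cxcr4 was at 4549 (2155 to 2469) and Lilr4b at 54.1 (35.05 to 38.01), and in Treg of vehicle replicate 3, Frmd5 was low at 42.8 (66.18 to 70.31).

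The venetoclax response differed between the subsets, by limma's test of the difference itself, for 25 of the named genes. Those with a lower response in Treg (Treg minus Tcon, log2) were Drc1 at -3.73, Fsd1l at -2.60, Bub1 at -2.31, Nuf2 at -2.29, Kif4 at -2.27, Myo6 at -2.24, Cenpf at -2.09, Coro2a at -2.08, Neb at -2.03, Pclaf at -1.99, Tpx2 at -1.95, Dtl at -1.88, Aspm at -1.79, Kntc1 at -1.78, Kif11 at -1.68, Nusap1 at -1.65, Top2a at -1.63, Bcl2 at -1.11 and Il2ra at -0.96. Those with a higher response in Treg were Prss12 at 1.99, Itga7 at 0.99, Trim13 at 0.98, H1f0 at 0.94, Il7r at 0.91 and Zfp316 at 0.91. Of the lists, 7 differed by camera's test with its preset correlation: T helper lineage (median 0.16), cell cycle (-0.92), oxidative phosphorylation (-0.11), glycolysis (-0.15), cholesterol synthesis (-0.28), common gamma chain signalling (-0.11) and ribosomal protein genes (-0.16). None of these list calls held with an estimated correlation, as given in the results.

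The splits argue against chance as the source of the gene counts. Among the 35 splits of 8 libraries into 4 and 4, only 1, the real one, gave as many genes in each comparison. No share below 1 in 35 can arise here, so the splits alone cannot exclude chance. The counts were 772 in Tcon (highest other split 2), 2164 in Treg (2) and 140 for the difference (0). For the numbers of lists, 16 of the 35 splits gave as many as the 9 called in Tcon (highest other 15), 6 as many as the 12 in Treg (15) and 12 as many as the 7 of the difference (11). Chance cannot be excluded for any of these 3 numbers of lists, and camera with its preset correlation called lists on splits with almost no changed genes. Of the single lists, only the real split gave so small a p for cell cycle in Tcon, for the Treg signature and common gamma chain signalling in Treg, and for cell cycle in the difference (1 of 35 each). Over 70 list tests about 2 would stand alone at 1 of 35 by chance and 4 did, none of which passed with an estimated correlation, so chance is not excluded for these list tests either. The single genes called within a list belong to the gene counts above. The 33 cell cycle genes called in Tcon and the 13 in the difference stand against at most 2 and 0 genes in the whole table in any other split. These values argue against chance for the called genes, within the limit of 35 splits. Camera at its preset correlation called the cell cycle list as such in 19 and 26 of the 35 splits, the real one among them. For every other called list, 2 or more of the 35 splits gave as small a p, so chance cannot be excluded for that p. In Tcon these were 2 for the anti-apoptotic genes and the Treg signature, 4 for common gamma chain signalling, 9 for immediate early genes, chaperones and glycolysis, 10 for effector and memory genes and 14 for cholesterol synthesis. In Treg they were 2 for naive and for T helper lineage genes, 3 for effector and memory genes, 4 for chaperones, 5 for mitochondrially encoded and for ribosomal protein genes, 10 for oxidative phosphorylation and cholesterol synthesis, and 11 for immediate early and interferon genes. For the difference they were 2 for glycolysis, 4 for common gamma chain signalling, 5 for cholesterol synthesis, 8 for T helper lineage, 15 for ribosomal protein genes and 17 for oxidative phosphorylation. If the replicate number pairs the libraries in Tcon, only 8 splits part every pair. The highest count among the 7 other than the real one was 0 genes. With 8 splits no share below 1 in 8 can arise.

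Of 30 immediate early genes, 6 fell in Tcon and 14 in Treg. Since 9 and 11 of the 35 splits gave the list as small a p, chance stays open for the list's p. Chance is argued against for the genes called, as part of the gene counts above, and 3 other explanations stay open. If the cells of vehicle mice had been under more dissociation stress, heat shock genes should be lower after venetoclax too. The 9 heat shock members of the chaperone list instead had medians of 0.59 (SE 0.27) in Tcon and 0.62 (SE 0.25) in Treg. These SEs are over genes and leave out the spread between libraries. Hspa1a (-1.08 and -0.32) and, in Tcon, Dnajb1 (-0.10), members with strong stress induction, lay on the other side, so the test does not decide. Handling of single mice or their cells may account for part of the fall. Over the 8 codes, deviations of the immediate early score from the group mean in Tcon and Treg had r = 0.88 (exact one-sided permutation p = 0.012 over 576 permutations within groups) and rho = 0.90 (exact p = 0.01). Without the vehicle and venetoclax codes of number 3, r was 0.99. Those 2 were left out because their Tcon deviations lay farthest from the median. Tcon and Treg libraries of a code also correlated at 0.46 to 0.77 across genes with a mean of at least 50, so these values do not single out handling. Handling that differed by treatment is confounded with treatment. With the Y-linked level in the fit the treatment effect on the score was -0.84 (SE 0.35) in Tcon and -0.65 (SE 0.21) in Treg, against -0.79 (SE 0.31) and -0.62 (SE 0.20) without it, which leaves uneven sex open as a part of it.

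Cell cycle genes rose in Tcon. Carry-over of Tregs with the average profile of the sorted Tregs is argued against, since Top2a rose from 14.8 to 62 CPM while Tregs of venetoclax mice held 51.3, so no share of them could bring the rise, and Foxp3 rose by 1.56 CPM (SE 1.24) with Tregs at 910. Uneven sex as the whole cause is argued against as well, since the treatment effect on the score was 1.2 (SE 0.14) with the Y-linked level in the fit and 1.18 (SE 0.13) without it. Among other cell types, more B cells (marker median -0.04, SE 0.32), myeloid cells (0.14, SE 0.29), dendritic cells (-0.34, SE 0.45) or NK cells (0.06, SE 0.32) are argued against. These medians lie more than 3 SEs below the cell cycle median of 1.05, with the larger of the SEs over genes and between libraries. For dendritic cells the margin is narrow and rests on 3 markers. MHC class II cells (-0.03, SE 0.56) stay open by that rule. Their levels in Tcon were 5.88 CPM with vehicle and 5.69 with venetoclax for Cd74, 2.02 and 2.1 for H2-Aa, 1.47 and 1.29 for H2-Ab1, and 1.9 and 1.46 for H2-Eb1. H2-DMb2 and Ciita lay below 1 CPM in both groups. Beside the rise of Top2a, these levels argue against class II cells that hold at least as much Cd74 RNA as Top2a RNA. Erythroid cells (-0.06, SE 0.71), stromal and endothelial cells (0.63, SE 0.30), plasma cells (-0.13, markers near the floor) and types with fewer than 3 measured markers (highest median 0.63) cannot be told apart from dividing Tcon. More division of Tcon themselves, or of a subset of them, therefore remains a hypothesis.

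Y-linked reads stood at part of the full level in 2 venetoclax codes, at 27.6% of it in venetoclax replicate 1 and 51.1% in venetoclax replicate 3. If male and female cells had been mixed before the sort, 3 X-linked genes that escape inactivation (Kdm6a, Eif2s3x and Kdm5c) should give the same male share. They gave 2.2% and 48.2%, a mean of 25.2%, with an SD of 20.7 between the codes without Y-linked reads, so mixing may be the source but is not shown. Loss of the Y chromosome, or of its expression, in part of the cells of male mice would leave the X-linked share at 100%; this is argued against for venetoclax replicate 1, 4.7 SDs below that, and stays open for venetoclax replicate 3, 2.5 SDs below. With the SE over the 6 gene values in place of that SD (8.3 and 10.8), the difference for venetoclax replicate 1 would exceed 3 SEs, which would count against plain mixing there, and the distances below 100% would be 11.8 and 4.8 SEs, which would count against loss of the Y chromosome in both.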

How the results depend on the processing

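The tests with the Y-linked level, with codes or libraries of number 3 left out, with the authors' adjusted p and with edgeR's TMM, with its filter or without, and the list test of the difference, were chosen only after the result was seen. Over all settings run for the named genes and for the lists called within a subset, none called without the block changed direction. Of 1306 values of the 60 called Tcon genes under other settings, 1166 stayed past the threshold and 140 fell below it; for 94 Treg genes these were 1957 and 101 of 2058, for 21 lists 265 and 50 of 315, and for 14 genes of the difference 107 and 71 of 178. Among the uncalled of the 10 genes fixed in advance, Il7r in Tcon passed without both libraries of number 3 (0.32, adjusted p = 0.00803), and Cd4 in Treg passed with DESeq2 (0.13, 0.0108) and by the authors' adjusted p (0.00981). A wider filter was void, since the tables hold no gene that a minimum of 1 read removes; edgeR without its filter gave 786 genes in Tcon and 2195 in Treg. Alternatives written for tables holding only the authors' comparison were run for the adjustment over genes with a mean of at least 50 (1205 in Tcon, 2253 in Treg) and otherwise not run. Counts without 1 or more libraries rest on fewer samples; apart from that the cause was not tested for the values below. Depth limits few named genes, all with a mean of at least 50 except some list members, and spread between replicates limits the rest.

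The 772 genes of Tcon became 1371 with DESeq2, 272 at an adjusted p of 0.01, 357 with a fold of at least 1.5, 1443 without both libraries of number 3, 116 without the 2 codes with partial Y-linked reads, 1257 by the authors' deposited adjusted p and 1205 by their p adjusted again. Leaving out 1 library gave 306 to 1244. With the replicate block there were 1880 genes; beyond the calls given in the results, the block changed no call that the text names, in Tcon or in the difference. The 2164 genes of Treg became 886 at an adjusted p of 0.01, 428 with a fold of at least 1.5, 1028 without both libraries of number 3 and 614 without the codes with partial Y-linked reads, and 1327 to 2198 with 1 library left out. In Treg the replicate block gave 2467 genes. The same-number correlations there were -0.04, 0.41, 0.26 and 0.39. Thus 1 of 4 lies below the bound of 0.1 set for every pair, and the number was not read as pairing the Treg libraries. As in Tcon, 3 of 4 pairs correlated best with their own number. The 140 genes of the difference became 389 with the replicate code as a block, 295 with DESeq2, 88 with a minimum mean of 5 CPM, 89 with the Y-linked level as a covariate and 4 without the codes with partial Y-linked reads, and 43 to 149 with 1 code left out. Dropping any of the 5 other pairs of venetoclax codes gave 81 to 242 genes in Tcon, 572 to 1246 in Treg and 4 to 61 for the difference. Each of these pairs but replicates 2 and 4 itself held replicate 1 or 3. Without replicates 2 and 4 there were 188 genes in Tcon, 1005 in Treg and 19 for the difference, more than without replicates 1 and 3. With a single such pair, whether the loss belongs to the codes with partial Y-linked reads cannot be told.

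The lists called numbered 0 with an estimated correlation in each subset, against 9 in Tcon and 12 in Treg, and 3 and 7 with fry. Ranks gave 10 and 13, the block 13 and 15 (in Treg it added cell cycle, 0.02, MHC class II, 0.0147, and erythroid, 0.0232), and 1 library left out 8 to 12 and 10 to 14. Fitted with the Y-linked level, 8 and 14 lists passed. That covariate also took the adjusted p of single Tcon genes over the threshold, as for Bcl2l1 in Tcon (0.0556), Maff in Tcon (0.0702), Irs2 in Tcon (0.0672) and Arc in Tcon (0.0683), and in the difference for Bub1 Treg minus Tcon (0.0656), Kif4 Treg minus Tcon (0.0867), Itga7 Treg minus Tcon (0.0932), Trim13 Treg minus Tcon (0.0627) and Zfp316 Treg minus Tcon (0.0563).

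Among the named genes, those that reversed were uncalled and had changes near 0. Without both libraries of number 3, Bcl2a1d in Tcon was at 0.191, Mcl1 in Tcon at -0.05, Bcl2 in Treg at -0.017 and Mcl1 in Treg at -0.045. Under the Y-linked covariate, Bcl2a1d in Tcon was at 0.086, Mcl1 in Tcon at -0.008 and Mcl1 in Treg at -0.013. Without the codes with partial Y-linked reads, Bcl2a1d in Tcon was at 0.116, Mcl1 in Tcon at -0.006, Bcl2 in Treg at -0.029 and Mcl1 in Treg at -0.071. With upper quartile scaling, Bcl2 in Treg was at -0.016, Il2ra in Treg at -0.005 and Mcl1 in Treg at -0.021, and with DESeq2 Mcl1 Treg minus Tcon was at 0.007. Leaving out 1 library gave -0.176 to 0.13 for Bcl2a1d in Tcon, -0.039 to 0.073 for Mcl1 in Tcon, -0.028 to 0.056 for Bcl2 in Treg, -0.004 to 0.055 for Il2ra in Treg, -0.022 to 0.048 for Mcl1 in Treg, -0.019 to 0.094 for Foxp3 Treg minus Tcon, -0.001 to 0.099 for Cd4 Treg minus Tcon and -0.036 to 0.023 for Mcl1 Treg minus Tcon.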

Other observations

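The tests of gene families below were chosen only after the result was seen.

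Families were read from gene symbols, 10 families in each subset. Fisher's exact test compared the share called with that of all genes (6.9% in Tcon, 19.5% in Treg), adjusted over all 20. Some called members, such as Ccr4, Il2rb and Il7r, also belong to the fixed lists. The family tests therefore restate in part calls given above. Chemokine receptors moved in Treg: 8 of 15 rose and none fell (median log2 0.54, Fisher's exact adjusted p = 0.0178), among them Cxcr4, Ccr4, Ccr6 and Ccr2. In Tcon 2 of 15 rose (adjusted p = 0.463). Of 31 interleukin receptor genes in Treg, 13 rose and 1 fell (median 0.26, adjusted p = 0.00696), among them Il18r1 (0.75), Il7r and Il1rl1; the symbol pattern also took in Il1rn, a receptor antagonist. In Tcon 5 rose and 2 fell (median 0.17, adjusted p = 0.0178). The rises in Tcon were Il2ra, Il2rb, Il21r, Il10ra (0.90) and Il12rb2 (0.88), and the falls were Il1rl2 (-0.47) and Il20rb (-1.09). With camera at an estimated correlation, the interleukin receptors had p = 0.0404 in Treg and 0.441 in Tcon, and the chemokine receptors in Treg 0.138, each adjusted over the families.

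Kruppel-like factors, transcription factors of quiescence and stress, fell in Tcon: 5 of 12 (median -0.42, Fisher's exact adjusted p = 0.00696; camera adjusted p = 0.441 with an estimated correlation). In Treg 4 of 11 fell and 2 rose (median -0.17, adjusted p = 0.0345; camera adjusted p = 0.248). Kinesins, the motors of the spindle among other tasks, rose in Tcon, 8 of 28 (median 0.18, adjusted p = 0.00696; adjusted p = 0.441 with an estimated correlation), while in Treg 5 of 29 rose (median 0.20, adjusted p = 0.732). The other families, TNF receptors, integrins, dual specificity phosphatases, GIMAP GTPases, histones and Rgs genes, had adjusted p values of 0.16 and above in both subsets by that test.

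Besides the treatment, the Y-linked level itself was tested in the fit that held it as a covariate. It was called for 1 gene in Tcon, Kdm6a (-0.80, SE 0.08, limma adjusted p = 0.0248), and for 8 in Treg. These were Ddx3y (11.4), Kdm5d (10.69), Kdm6a (-0.76), Eif2s3x (-0.64), Kdm5c (-0.48), Cxcr4 (0.76, limma adjusted p = 0.0324), Chdh (-0.63) and B4galnt4 (0.47). The level is the sum of Ddx3y and Kdm5d, so their own calls are no finding. In Tcon neither of them was called, so the test missed large effects there. The count in Tcon is therefore no measure of how many genes follow the level.

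Ribosomal protein genes have short transcripts, so their fall in Treg was set against other genes of like length or GC content. For the 69 of 71 with a transcript, the median was -0.27, against 0.00 for genes matched on length and 0.02 for genes matched on GC content. The matched genes left out the oxidative phosphorylation and mitochondrially encoded lists, which also fell in Treg (medians -0.14 and -0.25). Over all genes, shorter transcripts had lower log2 changes in Treg (Spearman 0.17 with length, -0.05 with GC content). A part played by length is therefore not excluded. With the count scalings the ribosomal median ran from -0.30 to -0.27.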
